A study of Mus musculus with 6 samples.

How the data were processed

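The deposited files are filtered gene by barcode matrices of raw UMI counts, 1 for each of 6 libraries of lung cells selected for CD45 with a positive-selection kit after enzymatic digestion and red cell lysis. The libraries are a WT vehicle, a KO vehicle, 2 WT LPS and 2 KO LPS libraries, from mice killed 4 h after an intraperitoneal injection. According to the submitters' processing notes, the counts were made by the authors with Cell Ranger 6.1.0 against mm10 and analysed with Seurat 4.1.0 in R 4.1.3. The annotation release is not given in the sources used here, and 32158 of the 32285 gene identifiers were found in GENCODE M21, which was used for gene positions. Whether the 2 LPS libraries of a genotype come from different animals is not given in the sources used here.

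The groups, comparisons, gene lists, tests, thresholds and first set of alternatives were fixed before the data were examined. Alternatives by sex marks and by mitochondrial share were added after the libraries were seen. Of 64428 barcodes, 61736 passed a filter of at least 200 detected genes and at most 10% mitochondrial UMIs. Doublet scores came from Scrublet as run in scanpy 1.11.5. Its automatic threshold called 0 or 1 cells in 5 libraries and 1923 in the other, so the highest-scoring cells of each library were removed instead. The number removed followed the doublet rate expected from the number of barcodes, 6.94% to 9.89% of cells, and left 56341 cells.

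Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, ribosomal, mitochondrial, haemoglobin, immunoglobulin segment and T cell receptor segment genes were left out. So were all genes of the fixed gene lists, sex-linked ones included, that were not class markers, and 1848 genes remained. They gave 30 principal components, a graph of 20 neighbours and 56 Leiden clusters at resolution 1.5 (leidenalg 0.10.2). A cluster was named by the marker list with the highest mean log2 fold over the other clusters, which had to reach 0.75 with at least 3 markers detected in 10% of cells. Clusters were called mixed and removed if the median doublet score was high, or if it was raised and the next list scored at least 0.7 of the best. This left 51704 cells, with 33 named clusters, 16 mixed ones removed and 7 without a name. The removed share (doublets and mixed clusters) was 15.3% to 18.3% of cells per library. Vehicle and LPS cells of a class often sat in different clusters: neutrophils in cluster 19 against 0, 1, 4 and 8, alveolar macrophages in 2 against 6, classical monocytes in 28 against 5 and 18, B cells in 3 against 10, 13 and 26, T cells in 7 against 12, NK cells in 11 against 17, endothelial cells in 35 and 49 against 20 and 44, interstitial macrophages in 41 against 32 and nonclassical monocytes in 31 against 22. The KO LPS alveolar macrophages were spread over clusters 2 and 6, a split that followed Xist and Y-linked transcripts, as given under Other observations.

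Counts were summed per library and class, and classes with at least 30 cells in every library were tested, which were 11 of 14. Free RNA of lysed cells was not subtracted in any gene test. Epithelial cells, plasmacytoid dendritic cells and platelets were too few. Gene tests used edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low-count filter by group, 1 coefficient per group and 2 residual degrees of freedom) in R 4.3.3, with Benjamini-Hochberg adjustment within each class and comparison at 0.05. The comparisons were LPS against vehicle averaged over genotypes, KO against WT among LPS libraries, and the difference between genotypes in the LPS response. DESeq2 1.42.0 was the other tool. KO against WT among vehicle libraries has 1 library a side and is given as values, with exact 95% Poisson intervals. Shares of cells were tested with edgeR across all 14 classes.

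A gene with 0 UMIs on the vehicle side is given as "at least", with 3 counts over that side's libraries as the floor, and one with 1 to 3 UMIs as a ratio with its counting interval. Genes were named by rule: per class the 3 largest rises and falls (6 in alveolar and interstitial macrophages, classical monocytes and neutrophils) among genes past the threshold. They also needed at least 50 CPM in the higher group and every library of one side beyond every library of the other. Predicted, ribosomal, mitochondrial, haemoglobin and receptor segment genes were left out. For the difference in response the 3 smallest p per class were taken, from each list up to 4 members with the smallest p, and Nos1, Nos2, Socs1, Socs3, Tnf, Il1b, Il6, Il10, Cxcl10 and Nfkbia always. For the vehicle libraries the rule took the 3 largest and 3 smallest ratios in the 4 main myeloid classes, among genes with at least 100 UMIs in 1 library. Some genes that these rules take are not reported here.

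The 15 tested gene lists were NF-kB target cytokines and chemokines, NF-kB pathway and feedback, SOCS and JAK-STAT feedback, interferon-stimulated genes, nitric oxide and arginine, M1-type and M2-type macrophage markers, acute-phase and neutrophil granule genes, glucocorticoid response, hypoxia and glycolysis, oxidative phosphorylation, MHC class II, adhesion and chemotaxis receptors, dissociation and immediate-early genes, and cell cycle. A sex-linked list served only to mark cells. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated and with fry. Cells were marked Xist-only or Y-only if they held only Xist or only Y-linked UMIs.

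A simulation with changes planted in 200 genes of each of 3 classes recovered 73.1% to 100% of 2-fold LPS changes and 62.7% to 97.0% of 2-fold differences between KO and WT, with 1.09% to 5.23% false calls. A 1.5-fold difference was recovered in 14.9% to 79.1% of genes. The planted genes lay above a floor of mean counts, their rises and falls alternated, and counts were drawn independently. The real comparisons called many more genes in these classes, so the rates need not carry over. A list planted at 2-fold was called by camera in all 6 simulations, with an adjusted p of 0.0401 to 0.131 under an estimated correlation. Analysis used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and the R package data.table (version 1.17.8).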

Results

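Lung cells positively selected for CD45 from wild-type (WT) and Nos1 knockout (KO) mice, 4 h after lipopolysaccharide (LPS) or vehicle, gave 51704 cells in 6 libraries. These were 1 vehicle library and 2 LPS libraries per genotype. Of the cells 48353 fell into 14 named classes and the rest had no name. In every library 11 of these classes held enough cells for a gene test. Changes are given as log2 values ± standard error, and LPS levels as mean ± SD of n = 2 libraries. Levels are CPM of the class after TMM scaling within that class, so comparisons of levels between classes are approximate. Plain CPM are used over whole libraries, for Xist in vehicle cells and for Y-only cells against the WT vehicle library. All p-values in this text measure only the spread between these libraries, which may be technical. The spread between the 2 LPS libraries of a group was compared with that between parts of 1 library. Their ratio ran from 0.93 (KO dendritic cells) to 2.09 (KO T cells). It was 1.05 in WT and in KO nonclassical monocytes, but 1.54 in WT and 1.74 in KO neutrophils. As the libraries are not known to be different animals, small p-values here need not hold between animals.

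LPS was followed by a large rise in neutrophils and classical monocytes and a fall in lymphocytes among the CD45-selected cells. Neutrophils made up 6.16% of cells in the WT vehicle library and 6.097% in the KO vehicle library, against 50.03 ± 1.01% in WT LPS and 38.5 ± 0.0865% in KO LPS libraries (n = 2 each). Classical monocytes went from 3.34% and 4.36% to 10.5 ± 0.414% and 9.69 ± 0.301%. B cells went from 27.1% and 25.2% to 7.84 ± 0.00923% and 13.6 ± 0.334%, T cells from 13.3% and 18.03% to 3.05 ± 0.303% and 5.21 ± 0.437%, and NK cells from 13.1% and 5.84% to 3.29 ± 0.174% and 2.26 ± 0.193%. Alveolar macrophages, the resident phagocytes of the airspace, went from 19.4% in each vehicle library to 8.99 ± 0.939% and 10.99 ± 0.456%.

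By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14 classes, the share of neutrophils rose by 2.84 ± 0.03 on the log2 scale (adjusted p = 2.09e-05). Classical monocytes rose by 1.40 ± 0.05, plasmacytoid dendritic cells by 1.24 ± 0.24 and platelets by 1.35 ± 0.35 (edgeR adjusted p = 0.000298, 0.0199 and 0.0393). B cells (-1.34 ± 0.02), T cells (-1.96 ± 0.08), NK cells (-1.69 ± 0.06), alveolar macrophages (-0.97 ± 0.08), interstitial macrophages (-0.67 ± 0.04) and nonclassical monocytes (-0.56 ± 0.08) fell. Endothelial (2.43 ± 0.210% in WT LPS), stromal and epithelial cells carry no CD45, so their shares depend on how complete the selection was. Shares are parts of a whole, and the neutrophil rise alone lowers the share of every other class. Leaving out 1 or the other WT LPS library ended the calls of plasmacytoid dendritic cells (edgeR adjusted p = 0.0852 and 0.0708), platelets (0.133 and 0.161) and nonclassical monocytes (0.066 and 0.0708). Without doublet removal nonclassical monocytes stood at 0.26 (edgeR adjusted p = 0.0153), and with cells named one by one at 0.37 (0.00077), while interstitial macrophages and plasmacytoid dendritic cells lost their calls (-0.17 and 0.24, adjusted p = 0.188 each).

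**Figure D1:**
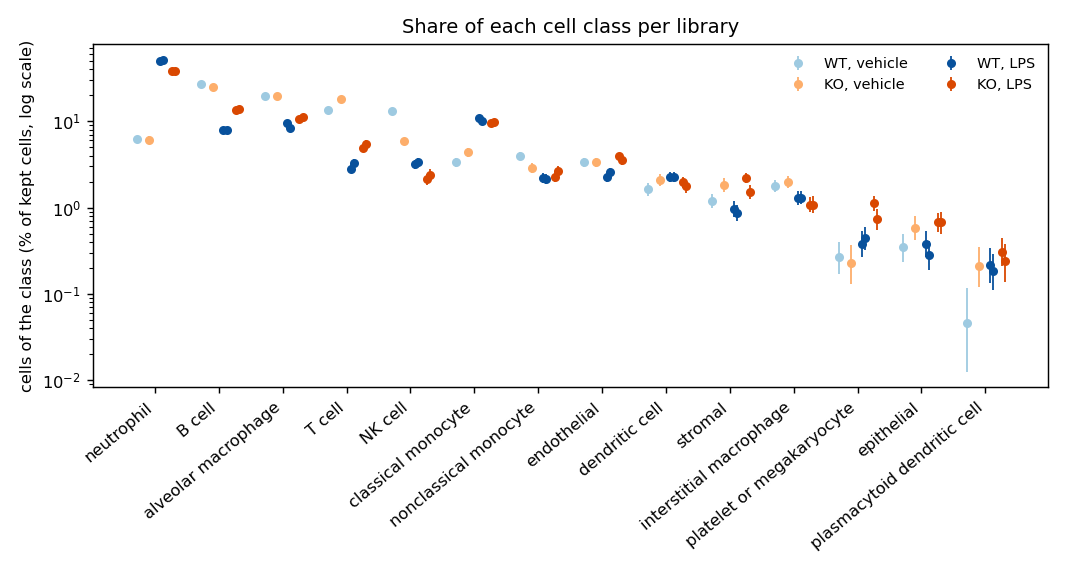
Percent of kept cells in each named class and library, on a log axis. Bars are exact binomial 95% intervals of each library, which measure the number of cells counted and not the spread between animals.

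Classical monocytes, the blood monocytes recruited to inflamed tissue, carried Saa3 and Sdc4 at far higher levels under LPS (4 LPS against 2 vehicle libraries). Saa3, a serum amyloid protein, rose by 13.05 ± 0.10 (8463-fold) to 36012 ± 215 CPM in WT. Syndecan Sdc4 had 0 UMIs in the vehicle libraries and rose at least 3134-fold, to 2908 ± 14.0 CPM in WT and 1524 ± 73.2 CPM in KO. Timp1, an inhibitor of matrix metalloproteinases, rose at least 591-fold. Edn1, the precursor of endothelin 1, rose at least 551-fold, the pentraxin Ptx3 at least 448-fold and U90926 at least 435-fold. The fractalkine receptor Cx3cr1 fell by 5.67 on the log2 scale, from 316 and 278 CPM to 3.88 ± 0.231 and 8.47 ± 0.842 CPM. Ypel3 (-5.99 ± 0.09), the lectin gene Clec2i (-5.57 ± 0.20), Rassf3 (-5.53 ± 0.15), Ldlrad3 (-5.43 ± 0.16) and the lipid transporter Abca9 (-5.23 ± 0.18) fell with it.

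Neutrophils turned on a lipase, nitric oxide synthase and an anti-inflammatory cytokine. Endothelial lipase Lipg rose at least 1715-fold, to 1777 ± 68.6 CPM in WT and 1034 ± 61.1 CPM in KO, from 0 UMIs in the vehicle libraries. Inducible nitric oxide synthase Nos2 rose at least 286-fold, Pdzk1ip1 at least 161-fold and the anti-inflammatory cytokine Il10 at least 73.6-fold. With 1 to 3 vehicle UMIs, Saa3 stood at a ratio of 9688 (2682 to 79999) and the interferon-inducible Ifi211 at 2465 (442 to 97355), with 95% intervals of counting error alone. Cd101, a surface protein of mature neutrophils, fell by 6.34 on the log2 scale (80.9-fold). The endoplasmic reticulum stress kinase Eif2ak3 (-4.05 ± 0.17), Mbp (-3.90 ± 0.10), Ttc7 (-3.83 ± 0.08) and integrin alpha 4, Itga4 (-3.85 ± 0.08), also fell.

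Alveolar macrophages raised neutrophil-attracting chemokines. Cxcl3 rose by 8.41 ± 0.12, from 3.88 CPM in WT and 1.64 CPM in KO vehicle cells to 1525 ± 151 and 489.8 ± 46.1 CPM. Cxcl1 rose by 7.07 ± 0.17 and Cxcl10, an interferon-induced chemokine for T cells, by 6.77 ± 0.16. Counts of Saa3 (8.74 ± 0.16), the siderophore-binding lipocalin Lcn2 (8.09 ± 0.13) and the schlafen gene Slfn4 (7.05 ± 0.18) rose in these droplets as well. Their WT LPS levels were 242 ± 26.0, 398 ± 25.4 and 135 ± 0.0748 CPM, no higher than the 259 ± 25.2, 430.3 ± 26.1 and 196 ± 0.456 CPM in T cells. Free RNA of lysed cells, which was not subtracted, adds counts per droplet and so gives lower CPM in deeper cells. In WT LPS the median depth was 14672 and 10839 UMIs per alveolar macrophage against 4873.5 and 3531 per T cell. Like CPM thus mean more UMIs per macrophage than per T cell, so free RNA stays open as only a part of the source of these counts. Saa3 stood at 36012 ± 215 CPM in monocytes and Lcn2 at 68445 ± 68.2 CPM in neutrophils. The largest falls were in the junction protein Afdn (-2.34 ± 0.09), Tifab (-2.04 ± 0.07), the G protein regulator Rgs2 (-1.97 ± 0.06), Tppp3 (-1.89 ± 0.05), keratin Krt19 (-1.86 ± 0.05) and the retinaldehyde reductase Dhrs3 (-1.74 ± 0.05). In interstitial macrophages counts of Saa3 (4105-fold) and Edn1 (at least 481-fold) rose. So did those of the neutrophil genes Lcn2 (10.22 ± 0.21) and cathelicidin Camp (at least 464-fold), with Ngp at a ratio of 2850.1 (511 to 112613) and Lipg at 1543 (276 to 60979). S100a8, another neutrophil gene, stood at 12316 ± 1955 CPM in these WT LPS cells against 113557 ± 5899.7 CPM in neutrophils, so neutrophil RNA in these droplets stays open as a source. Their largest falls were in Cx3cr1 (-4.58 ± 0.21), Gpr34 (-3.77 ± 0.25), Krt19 (-3.88 ± 0.23) and the lymphocyte genes Mzb1 (-4.66 ± 0.27), Thy1 (-4.57 ± 0.28) and Fcer2a (-4.30 ± 0.23), while lymphocytes fell in share.

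Outside the 4 main myeloid classes Cxcl10 was among the largest rises. It rose at least 16386-fold in endothelial cells, to 21359.8 ± 1482 CPM in WT and 11149 ± 832 CPM in KO, and by 12.27 ± 0.20 in B cells, 9.32 ± 0.15 in T cells, 11.77 ± 0.20 in stromal cells and 10.45 ± 0.17 in nonclassical monocytes. In WT LPS it stood at 854 ± 50.8 CPM in B cells and 1940.4 ± 65.1 CPM in T cells against 130.3 ± 19.1 CPM in alveolar macrophages, so free RNA stays open as a part of the rise in lymphocytes. Cxcl9, another interferon-induced chemokine, rose at least 1072-fold in endothelial cells, which lost Glp1r (-4.98 ± 0.12), the dynein gene Dnah8 (-4.69 ± 0.30) and elastin, Eln (-4.30 ± 0.28). Counts of Lcn2 rose in B cells (9.37 ± 0.23), T cells (8.69 ± 0.20), NK cells (8.14 ± 0.37), nonclassical monocytes (10.27 ± 0.19), endothelial cells (13.22 ± 0.33) and, at least 2183-fold, in stromal cells. In WT LPS they stood at 467 ± 8.65 CPM in B cells and 430.3 ± 26.1 CPM in T cells, like levels, so free RNA stays open as a source. The same holds for Saa3 counts in NK cells (at least 271-fold, to 285 ± 17.5 CPM in WT against 303 ± 25.4 CPM in B cells). Ifi204 stood in NK cells at a ratio of 1058 (292 to 8744). Falls included Hhex, Pgap1 and Trim7 in B cells (-3.89 ± 0.12, -3.84 ± 0.09 and -3.83 ± 0.11), and Hsd11b1, Kif21b and the T cell receptor regulator Cd5 in T cells (-3.70 ± 0.22, -3.38 ± 0.17 and -3.35 ± 0.15). NK cells lost Mxd4 (-4.35 ± 0.19), dendritic cells Arhgap18 (-3.56 ± 0.17) and Cx3cr1 (-3.54 ± 0.35), nonclassical monocytes Mdm1 (-6.54 ± 0.42), Cx3cr1 (-6.07 ± 0.16) and Add3 (-5.86 ± 0.17), and stromal cells the clock gene Dbp (-5.41 ± 0.47).

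Socs1, named in the series title, and the inflammatory genes fixed beside it rose with LPS in the main myeloid classes. Socs1 encodes an inhibitor of JAK-STAT signalling and rose by 5.74 ± 0.12 in neutrophils, 3.82 ± 0.13 in classical monocytes, 3.50 ± 0.15 in interstitial macrophages and 2.36 ± 0.24 in alveolar macrophages (edgeR adjusted p = 1e-17, 2.37e-12, 4.09e-14 and 1.01e-08). Its relative Socs3 rose by 5.69 ± 0.09 in alveolar macrophages and 3.57 ± 0.06 in classical monocytes. Nfkbia, which encodes the NF-kB inhibitor IkB alpha, rose by 3.39 to 4.37 in the 4 classes. Tumour necrosis factor, Tnf, rose by 4.23 ± 0.07 in alveolar macrophages and 4.41 ± 0.11 in neutrophils, and interleukin 1 beta, Il1b, by 5.01 ± 0.07 and 1.79 ± 0.04. The Il1b rise in neutrophils is little larger than the shift of -1.56 between plain CPM and TMM scaling there. Il6 rose by 5.71 ± 0.34 in alveolar macrophages and 4.58 ± 0.24 in classical monocytes, and Nos2 at least 337-fold in classical monocytes.

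NF-kB target cytokines and chemokines rose as a group. In classical monocytes 16 of 17 rose and 1 fell (16 and 1 adjusted over the list alone; median log2 3.95, 3.94 with bounds; camera adjusted p = 1.03e-06, adjusted p = 0.237 with an estimated correlation). Ccl4 stood at 7.55 and Ccl3 at 4.49. In neutrophils 15 of 17 rose and 1 fell (15 and 2 adjusted over the list alone; median log2 5.02, 4.41 with bounds; camera adjusted p = 0.000224, adjusted p = 0.185 with an estimated correlation). Ccl4 stood at 8.09 and Cxcl2 at 5.02. In alveolar macrophages 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone; median log2 4.45; camera adjusted p = 6.44e-11, adjusted p = 0.19 with an estimated correlation). Cxcl2 stood at 5.54. In interstitial macrophages 17 of 17 rose and 0 fell (17 and 0 adjusted over the list alone; median log2 4.81; camera adjusted p = 4.05e-12, adjusted p = 0.112 with an estimated correlation). Of the genes of the NF-kB pathway and its feedback, 18 of 18 rose and 0 fell (18 and 0 adjusted over the list alone; median log2 2.00; camera adjusted p = 2.6e-12, adjusted p = 0.19 with an estimated correlation) in alveolar macrophages, among them the deubiquitinase Tnfaip3 (3.67) and Nfkbiz (4.08). In neutrophils 18 of 18 rose and 0 fell (18 and 0 adjusted over the list alone; median log2 3.71; camera adjusted p = 4.3e-07, adjusted p = 0.214 with an estimated correlation). The manganese superoxide dismutase Sod2 stood at 7.49. In classical monocytes 17 of 18 rose and 0 fell (17 and 0 adjusted over the list alone; median log2 2.19; camera adjusted p = 9.16e-07, adjusted p = 0.237 with an estimated correlation). The survival gene Bcl2a1b stood at 7.26.

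Interferon-stimulated genes rose nearly without exception. In neutrophils 32 of 32 rose and 0 fell (32 and 0 adjusted over the list alone; median log2 5.90, 5.56 with bounds; camera adjusted p = 6.21e-12, adjusted p = 0.185 with an estimated correlation). Ifit1 stood at 7.81 and the GTPase Gbp2 at 6.97. In classical monocytes 32 of 32 rose and 0 fell (32 and 0 adjusted over the list alone; median log2 3.18; camera adjusted p = 1.39e-13, adjusted p = 0.262 with an estimated correlation). In alveolar macrophages 31 of 32 rose and 0 fell (31 and 0 adjusted over the list alone; median log2 3.45; camera adjusted p = 8.96e-18, adjusted p = 0.19 with an estimated correlation). In T cells 32 of 32 rose and 0 fell (32 and 0 adjusted over the list alone; median log2 4.73, 4.53 with bounds; camera adjusted p = 6.07e-29, adjusted p = 0.0892 with an estimated correlation). SOCS and JAK-STAT feedback genes rose too. In neutrophils 10 of 14 rose and 1 fell (11 and 1 adjusted over the list alone; median log2 1.34; camera adjusted p = 0.00138, adjusted p = 0.185 with an estimated correlation). That median is smaller than the shift of -1.56 between plain CPM and TMM scaling there. In alveolar macrophages 8 of 14 rose and 3 fell (8 and 3 adjusted over the list alone; median log2 0.80; camera adjusted p = 0.00938, adjusted p = 0.413 with an estimated correlation). Cish stood at 2.87 and Il1rn, the interleukin 1 receptor antagonist, at 1.30. Of the acute-phase and neutrophil granule genes counted in alveolar macrophages 12 of 13 rose and 1 fell (12 and 1 adjusted over the list alone; median log2 4.79, 4.23 with bounds; camera adjusted p = 2.94e-07, adjusted p = 0.19 with an estimated correlation). Haptoglobin, Hp, stood at 4.23, and its WT LPS level was 85.1 ± 3.78 CPM against 86.6 ± 15.1 CPM in T cells. As T cells hold fewer UMIs per cell, like CPM mean more Hp UMIs per macrophage, and free RNA stays open as only a part of them.

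Of the macrophage lists, M1-type markers gave a call in alveolar macrophages, where 13 of 14 rose and 1 fell (13 and 1 adjusted over the list alone; median log2 2.84; camera adjusted p = 2.51e-08, adjusted p = 0.19 with an estimated correlation). Slc7a11 stood at 2.98 and Tlr2 at 1.55. Of the M2-type markers 10 of 16 rose and 2 fell (10 and 2 adjusted over the list alone; median log2 0.49; camera adjusted p = 0.00938, adjusted p = 0.19 with an estimated correlation). Ccl17 stood at 5.49 and Klf4 at -0.92. In interstitial macrophages the M2-type median was -0.06 while the mean was 0.92 and the test pointed up. Of the glucocorticoid response genes 12 of 15 rose and 1 fell (12 and 1 adjusted over the list alone; median log2 1.36; camera adjusted p = 1.01e-05, adjusted p = 0.19 with an estimated correlation). Fkbp5 stood at 2.50 and Klf9 at 2.26. Of the hypoxia and glycolysis genes 14 of 22 rose and 3 fell (14 and 3 adjusted over the list alone; median log2 0.37; camera adjusted p = 0.0033, adjusted p = 0.37 with an estimated correlation). Glucose transporter Slc2a1 stood at 3.24 and hexokinase Hk2 at 1.90. Of the dissociation and immediate-early genes 12 of 19 rose and 3 fell (13 and 3 adjusted over the list alone; median log2 0.81; camera adjusted p = 2.05e-05, adjusted p = 0.19 with an estimated correlation). Ier3 stood at 4.93 and Egr1 at 4.29. The cell cycle list pointed down, as 2 of 17 rose and 9 fell (2 and 9 adjusted over the list alone; median log2 -0.41; camera adjusted p = 0.0252, adjusted p = 0.216 with an estimated correlation). Mcm2 stood at -1.20 and Mcm3 at -0.63.

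Some lists moved in parts. Of the nitric oxide and arginine genes in alveolar macrophages 6 of 12 rose and 2 fell (6 and 2 adjusted over the list alone; median log2 0.72; camera adjusted p = 0.0723, adjusted p = 0.413 with an estimated correlation). Gch1, which makes a cofactor of nitric oxide synthases, stood at 1.68 and Slc7a2, an arginine transporter, at 1.44. Of the adhesion and chemotaxis receptors in neutrophils 15 of 20 rose and 3 fell (15 and 3 adjusted over the list alone; median log2 1.03; camera adjusted p = 0.0148, adjusted p = 0.41 with an estimated correlation). The direction of this median depends on the scaling, as plain CPM moved the median neutrophil gene by -1.56 against TMM. The formyl peptide receptor Fpr2 stood at 3.88, Fpr1 at 3.68 and Ccr1 at 1.79. In B cells MHC class II genes fell: 2 of 14 rose and 11 fell (3 and 11 adjusted over the list alone; median log2 -1.03; camera adjusted p = 0.0048, adjusted p = 0.256 with an estimated correlation). In alveolar macrophages 7 of 14 rose and 4 fell (7 and 4 adjusted over the list alone; median log2 0.22; camera adjusted p = 0.234, adjusted p = 0.6 with an estimated correlation) of that list, with H2-Aa at 0.51 and Cd80 at 1.09. Of the oxidative phosphorylation genes 15 of 24 rose and 1 fell (15 and 1 adjusted over the list alone; median log2 0.27; camera adjusted p = 0.00462, adjusted p = 0.413 with an estimated correlation) there. Atp5g1 stood at 0.52 and Uqcrb at 0.39.

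By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6979 of 12188 genes changed with LPS in alveolar macrophages (3512 rose, 3467 fell), 6977 in classical monocytes (3658 and 3319), 6115 in neutrophils (3629 and 2486) and 6243 in interstitial macrophages (3050 and 3193). The other classes gave 7554 in B cells, 6363 in endothelial cells, 4862 in nonclassical monocytes, 4809 in dendritic cells, 4441 in T cells, 4029 in NK cells and 2209 in stromal cells. DESeq2 split its calls differently: 2336 rose and 1530 fell in alveolar macrophages, 1994 and 1026 in interstitial macrophages, 1589 and 709 in dendritic cells, 1354 and 757 in T cells, 1154 and 629 in NK cells and 693 and 124 in stromal cells. The vehicle side is 1 library per genotype, and in WT it carries Y-linked transcripts where the LPS libraries carry Xist, so sex differs with treatment there. With an estimated correlation 0 of 15 lists passed in any class. Fry called 9 to 15 of the lists per class and camera 7 to 12. In neutrophils, plain CPM scaling moved the median gene by -1.56 on the log2 scale against TMM scaling.

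**Figure D2:**
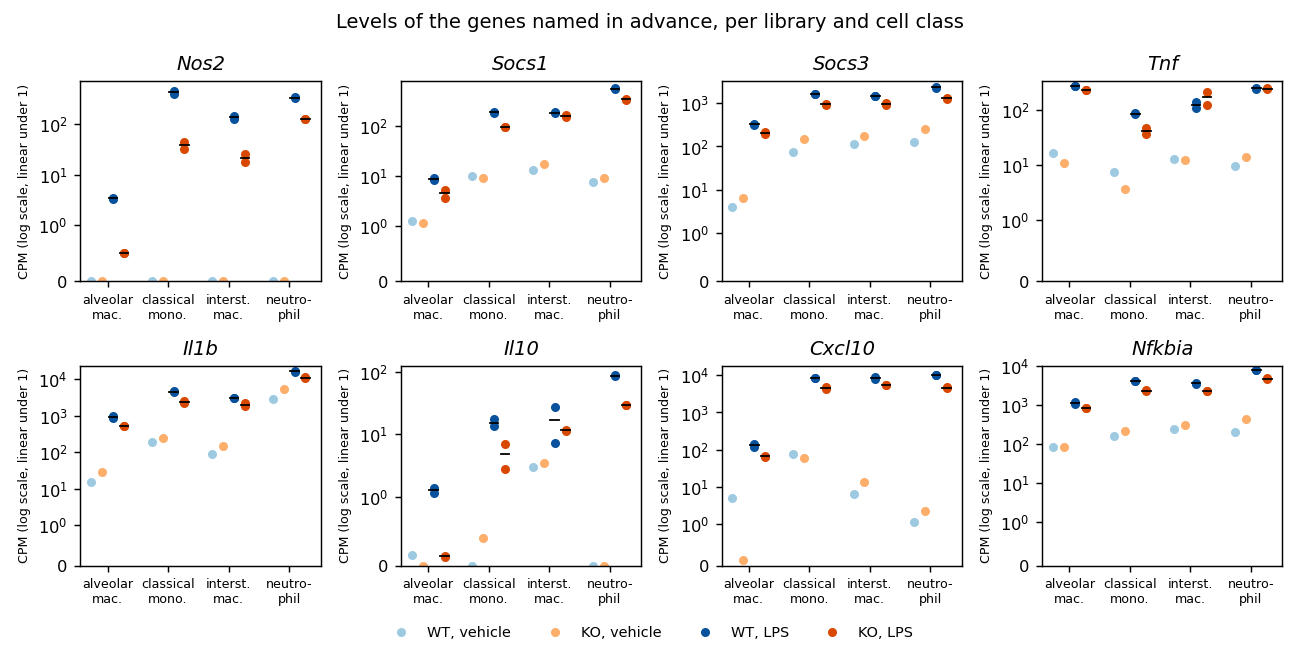
Level of Nos2, Socs1, Socs3, Tnf, Il1b, Il10, Cxcl10 and Nfkbia in 4 myeloid classes, in CPM of the class after TMM scaling. Points are libraries and bars are group means, on an axis that is linear near 0 and logarithmic above.

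Nos1 itself was close to absent in every library. It held 0 to 3 UMIs per library, at 0.0571 ± 0.0218 CPM in KO LPS and 0.00780 ± 0.0110 CPM in WT LPS libraries (n = 2 each), so these counts check nothing about the knockout. Among kept cells of the LPS libraries neutrophils had a lower share in KO, at 38.5 ± 0.0865% against 50.03 ± 1.01% in WT (-0.38 ± 0.03, edgeR adjusted p = 0.00377). The share was higher for B cells (0.79 ± 0.03, edgeR adjusted p = 0.00142), T cells (0.76 ± 0.11), endothelial cells (0.62 ± 0.10) and epithelial cells (1.03 ± 0.16), each of the last 3 at adjusted p = 0.0172. Platelets (1.20 ± 0.29) and stromal cells (1.05 ± 0.24) were higher as well, and NK cells (-0.55 ± 0.09) and dendritic cells (-0.27 ± 0.07) lower. A lower share of neutrophils by itself raises the share of every other class. Classical monocytes (-0.11, edgeR adjusted p = 0.105) and alveolar macrophages (0.29, adjusted p = 0.0677) gave no call. Each of the 9 calls above was lost when some 1 of the LPS libraries was left out, and the epithelial difference turned to -0.22 with cells named one by one. In Xist-only cells neutrophils stood at -0.87 (edgeR adjusted p = 0.00145) and B cells at 1.08 (3.51e-05). In these NK cells stood at -0.10 and dendritic cells at -0.17 (edgeR adjusted p = 0.452 and 0.24), and classical monocytes were lower, at -0.57 (0.00323).

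The KO LPS libraries held cells with Xist, the transcript of the inactive X chromosome, and cells with Y-linked transcripts. Of cells marked by only 1 of these, 40.6% and 37.0% carried Y-linked transcripts alone (Y-only cells), against 0.0147% in the KO vehicle library and 0.0707% and 0.0163% in the WT LPS libraries. The WT vehicle library held 5091 Y-only and 2 Xist-only cells. In the KO LPS libraries, Y-only cells made up 63.8% and 66.2% of singly marked neutrophils, 59.4% and 52.5% of classical monocytes, 52.1% and 40.7% of alveolar macrophages and 8.43% and 8.60% of B cells. Values for Xist-only KO cells, an alternative added after this was seen, are therefore given beside part of the gene results below. Interstitial macrophages, dendritic cells, NK cells, nonclassical monocytes and stromal cells had no such fit.

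Classical monocytes of KO LPS lungs carried far less Nos2, at 38.3 ± 9.42 CPM against 427 ± 50.6 CPM in WT (-3.53 ± 0.12, edgeR adjusted p = 9.27e-11, n = 2 and 2). Nos2 was lower also in neutrophils (-1.40 ± 0.04), interstitial macrophages (-2.61 ± 0.21), alveolar macrophages (-2.74 ± 0.41) and dendritic cells (-2.82 ± 0.22). In Xist-only cells it stood at -1.95 in classical monocytes, -1.20 in neutrophils and -2.68 in alveolar macrophages. Socs1 was lower in neutrophils, at 339 ± 13.6 CPM in KO against 552 ± 30.1 CPM in WT (-0.70 ± 0.05), in classical monocytes (-0.97 ± 0.06) and in alveolar macrophages (-1.004 ± 0.21). In interstitial macrophages Socs1 stood at -0.21 ± 0.13 (edgeR adjusted p = 0.398). In Xist-only cells the Socs1 difference was -0.21 in neutrophils (edgeR adjusted p = 0.0283), 0.10 in classical monocytes (0.517) and -0.38 in alveolar macrophages (0.334). Il10 was lower in neutrophils (-1.58 ± 0.06, -0.87 in Xist-only cells) and Tnf there stood at -0.04 ± 0.04 (edgeR adjusted p = 0.547).

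In classical monocytes the collagenase Mmp13 (-2.91 ± 0.11), granulocyte colony-stimulating factor Csf3 (-2.74 ± 0.17), Lipg (-2.28 ± 0.08), Ptx3 (-2.23 ± 0.08) and metallothionein Mt2 (-2.21 ± 0.09) were lower in KO. In Xist-only cells they stood at -1.31, -1.30, -0.99, -0.44 and -1.12. Higher in KO were lipoprotein lipase Lpl (3.05 ± 0.09, 119 ± 6.85 CPM in KO against 14.3 ± 0.836 CPM in WT), the collagen receptor Lair1 (2.71 ± 0.11), Ddit4, an inhibitor of mTORC1 (2.53 ± 0.11), the ERK phosphatase Dusp6 (2.12 ± 0.09), the adaptor Dok2 (2.07 ± 0.07) and Ceacam1 (1.95 ± 0.09). In Xist-only cells these stood at 0.82, 0.53 (edgeR adjusted p = 0.131), 1.79, 0.70, 0.78 and 0.71.

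In neutrophils the acute-phase genes Saa1 (-3.42 ± 0.11) and Saa3 (-1.61 ± 0.04), the adenosine receptor Adora2b (-1.55 ± 0.07), Fnip2 (-1.52 ± 0.08) and the MHC class I gene H2-Q7 (-1.41 ± 0.07) were lower in KO. In Xist-only cells they stood at -3.64, -1.81, -0.86, -1.24 and -0.86. The lysosomal trafficking regulator Lyst (1.75 ± 0.06, 0.47 in Xist-only cells), Ccpg1 (1.56 ± 0.06, 0.73) and Dock5 (1.17 ± 0.08, 0.77) were higher. Mtus1 (1.31 ± 0.07), Unc119 (1.27 ± 0.07) and Tmem71 (1.25 ± 0.07) were higher too, and gave no call in Xist-only cells (edgeR adjusted p = 0.32, 0.215 and 0.488).

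In alveolar macrophages the chemokine Ccl17 (-2.18 ± 0.07), Slfn4 (-2.04 ± 0.08), Saa3 (-1.99 ± 0.07), AA467197 (-1.83 ± 0.09), the neutrophil collagenase Mmp8 (-1.81 ± 0.08) and S100a6 (-1.67 ± 0.09) were lower in KO. In Xist-only cells they stood at -1.48, -1.92, -2.02, -1.20, -1.58 and -1.36. KO LPS levels of Saa3 and Slfn4 were 60.9 ± 0.680 and 31.9 ± 6.61 CPM there, no higher than the 77.5 ± 17.9 and 56.9 ± 18.6 CPM of T cells. The median depth in KO LPS was 13380 and 9741 UMIs per alveolar macrophage against 4428 and 3060 per T cell. These levels thus mean more UMIs per macrophage than per T cell, and free RNA stays open as only a part of these 2 differences. Isocitrate dehydrogenase Idh1 (1.28 ± 0.06, 0.53 in Xist-only cells) was higher. Dhrs3 (1.66 ± 0.07), the amino acid transporter Slc43a2 (1.53 ± 0.08), Pwwp3a (1.16 ± 0.08) and Ap1s2 (1.16 ± 0.06) were higher too. In Xist-only cells these 4 stood at -0.09, 0.16, -0.17 and 0.05 with no call (edgeR adjusted p = 0.559, 0.396, 0.391 and 0.684).

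Interstitial macrophages of KO LPS lungs carried less Cxcl13, a chemokine for B cells (-2.65 ± 0.28, 1037 ± 726 CPM in KO against 6578 ± 1577 CPM in WT). Cxcl5 (-4.41 ± 0.71), Saa1 (-4.29 ± 0.58), the prostaglandin E synthase Ptges (-2.15 ± 0.31) and the protease inhibitor Slpi (-2.06 ± 0.17) were lower as well. Saa1 was also lower in KO neutrophils, so neutrophil RNA in these droplets stays open as a part of its difference. In interstitial macrophages Ccl17 was higher (2.93 ± 0.39, 909 ± 620.5 CPM), the opposite direction to alveolar macrophages. Ets1 (1.88 ± 0.20), Fosb (1.79 ± 0.25) and Net1 (1.73 ± 0.22) were higher with it. Mucl1 stood at a ratio of 445 (79.4 to 17636), nearly all from 1 library (109.5 ± 148 CPM).

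In other classes, KO B cells had less lamin, Lmna (-3.46 ± 0.18), S100a6 (-2.59 ± 0.17) and Zbtb32 (-2.39 ± 0.20), and more of the histones Hist1h1b (2.09 ± 0.17) and Hist1h1c (1.77 ± 0.10). The mix of B cell clusters differed, with 465 and 312 KO LPS cells against 130 and 132 WT LPS cells in cluster 13, so a part of these differences may be one of mix. In Xist-only B cells they stood at -3.30, -2.58, -2.03, 1.96 and 1.75. T cells had less Oas1a (-1.79 ± 0.25, -1.72 in Xist-only cells) and more Cd3g (1.32 ± 0.13, 1.03), and fewer Saa3 counts (-1.69 ± 0.13, -1.88), for which free RNA stays open as a source. Oas1a lies within 20 Mb of Nos1 on the same chromosome, so DNA of another strain around Nos1 stays open for it. NK cells had less osteopontin, Spp1 (-3.43 ± 0.56), and Ccl9 (-2.26 ± 0.27) and more lymphotoxin beta, Ltb (2.38 ± 0.35), and granzyme Gzmc (1.84 ± 0.33). Dendritic cells had less Ptx3 (-2.65 ± 0.29) and more Qpct (2.88 ± 0.27) and Itgae (2.50 ± 0.23). Endothelial cells had less Ubd (-2.69 ± 0.23) and Cd74 (-2.33 ± 0.13). Their Myzap (3.43 ± 0.15) and Clec1a (3.08 ± 0.14) were higher, at 0.47 and 0.08 in Xist-only cells with no call (edgeR adjusted p = 0.445 and 0.919). Nonclassical monocytes had less Spp1 (-2.25 ± 0.41) and more Ceacam1 (2.60 ± 0.24) and Ddit4 (2.27 ± 0.31). Stromal cells had less eotaxin, Ccl11 (-2.88 ± 0.49), Ccl7 (-2.29 ± 0.28) and the matrix metalloproteinase Mmp3 (-2.13 ± 0.23) and more Eln (2.13 ± 0.26).

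Interferon-stimulated genes were lower in KO LPS neutrophils, in all cells and in Xist-only cells. Over all neutrophils 0 of 32 were higher and 31 were lower (0 and 31 adjusted over the list alone; median log2 -0.77; camera adjusted p = 3.29e-17, adjusted p = 0.147 with an estimated correlation). Gbp3 stood at -1.15, Cxcl10 at -1.12, Ifit1 at -1.02 and Gbp5 at -0.94. In Xist-only neutrophils 30 of 31 were lower, with a median of -0.67. Under plain CPM scaling the median over all neutrophils was -0.44. The median mitochondrial share of neutrophils was 0.214% and 0.243% in WT LPS against 0.351% and 0.360% in KO LPS libraries. In classical monocytes 0 of 32 were higher and 32 were lower (0 and 32 adjusted over the list alone; median log2 -0.76; camera adjusted p = 7.67e-15, adjusted p = 0.325 with an estimated correlation). Usp18 stood at -1.18 and Rsad2 at -1.11. In Xist-only monocytes 12 were higher and 6 lower, with a median of 0.10. In alveolar macrophages 1 of 32 were higher and 22 were lower (1 and 24 adjusted over the list alone; median log2 -0.72; camera adjusted p = 7.29e-10, adjusted p = 0.403 with an estimated correlation). Irf7 stood at -1.49. In Xist-only cells there 20 were lower and 0 higher, with a median of -0.44.

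NF-kB target cytokines and chemokines were lower in KO. In classical monocytes 0 of 17 were higher and 14 were lower (0 and 14 adjusted over the list alone; median log2 -0.88; camera adjusted p = 1.65e-07, adjusted p = 0.325 with an estimated correlation). Ccl3 stood at -1.53, Ccl4 at -1.27 and Ccl7 at -1.77. Xist-only cells there had 5 higher and 5 lower (median -0.09). In neutrophils 1 of 17 were higher and 14 were lower (1 and 14 adjusted over the list alone; median log2 -0.62; camera adjusted p = 5.18e-06, adjusted p = 0.195 with an estimated correlation). Ccl4 stood at -1.15 and Ccl3 at -0.96. Among Xist-only cells were 1 higher and 9 lower of 16 (median -0.59). In alveolar macrophages 0 of 17 were higher and 12 were lower (0 and 12 adjusted over the list alone; median log2 -0.64; camera adjusted p = 0.000195, adjusted p = 0.409 with an estimated correlation). Cxcl3 stood at -1.64. Xist-only cells there had 5 higher and 2 lower (median 0.10). For the NF-kB pathway and its feedback, in classical monocytes 0 of 18 were higher and 18 were lower (0 and 18 adjusted over the list alone; median log2 -0.61; camera adjusted p = 1.62e-08, adjusted p = 0.325 with an estimated correlation). Tnfaip3 stood at -1.30 and Bcl3 at -1.28. Xist-only cells there had 5 higher and 0 lower (median 0.08). In neutrophils 0 of 18 were higher and 16 were lower (0 and 17 adjusted over the list alone; median log2 -0.43; camera adjusted p = 6.46e-08, adjusted p = 0.29 with an estimated correlation). Tnfaip3 stood at -0.75. Among Xist-only cells were 10 lower (median -0.38). Plain CPM scaling moved the median neutrophil gene by 0.33, most of the size of this list median.

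SOCS and JAK-STAT feedback genes were lower in neutrophils, where 0 of 14 were higher and 9 were lower (0 and 9 adjusted over the list alone; median log2 -0.29; camera adjusted p = 0.00329, adjusted p = 0.277 with an estimated correlation). Il1rn stood at -0.86 and Socs3 at -0.83. In classical monocytes 0 of 14 were higher and 8 were lower (0 and 8 adjusted over the list alone; median log2 -0.24; camera adjusted p = 0.0172, adjusted p = 0.325 with an estimated correlation). Il1rn stood at -1.38. Xist-only cells there had 2 higher and 2 lower. Plain CPM scaling moved the median gene by 0.33 in neutrophils and 0.25 in classical monocytes against TMM scaling, as much as the medians of these 2 lists, and the neutrophil and monocyte lists below share that limit. Of the acute-phase and granule genes in alveolar macrophages 0 of 13 were higher and 11 were lower (0 and 11 adjusted over the list alone; median log2 -1.06; camera adjusted p = 1.19e-05, adjusted p = 0.409 with an estimated correlation). Lcn2 stood at -1.45 and Hp at -1.29, against -0.99 and -0.88 in T cells, so free RNA stays open as a part of their source. Among Xist-only cells were 8 lower (median -1.01). Of the MHC class II genes there 1 of 14 were higher and 10 were lower (1 and 10 adjusted over the list alone; median log2 -0.73; camera adjusted p = 0.00214, adjusted p = 0.409 with an estimated correlation). H2-Aa stood at -1.09 and Cd74 at -1.03. Xist-only cells there had 1 higher and 3 lower (median -0.07). Of the M1-type markers in neutrophils 0 of 15 were higher and 12 were lower (0 and 12 adjusted over the list alone; median log2 -0.55; camera adjusted p = 1.56e-05, adjusted p = 0.195 with an estimated correlation). Marcks stood at -0.60 and Cd38 at -0.93.

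Of the nitric oxide and arginine genes in neutrophils 0 of 11 were higher and 4 were lower (0 and 4 adjusted over the list alone; median log2 -0.10; camera adjusted p = 0.0949, adjusted p = 0.34 with an estimated correlation). Arginase Arg2 stood at -0.82 and Gch1 at -0.45. Of the hypoxia and glycolysis genes in classical monocytes 13 of 22 were higher and 4 were lower (13 and 4 adjusted over the list alone; median log2 0.39; camera adjusted p = 0.0812, adjusted p = 0.503 with an estimated correlation). Slc16a3 stood at 1.43, Tpi1 at 1.06 and Pfkfb3 at -1.49. Of the immediate-early genes there 9 of 19 were higher and 4 were lower (10 and 4 adjusted over the list alone; median log2 0.24; camera adjusted p = 0.0621, adjusted p = 0.503 with an estimated correlation). Fos stood at 1.04 and Jun at 0.78. Of the glucocorticoid response genes there 3 of 16 were higher and 5 were lower (3 and 5 adjusted over the list alone; median log2 -0.03; camera adjusted p = 0.864, adjusted p = 0.903 with an estimated correlation). Fkbp5 stood at 1.60, and the mean of the list was 0.15 where the median was -0.03. Of the M2-type markers there 5 of 17 were higher and 5 were lower (5 and 5 adjusted over the list alone; median log2 0.17; camera adjusted p = 0.692, adjusted p = 0.895 with an estimated correlation). Tgfb1 stood at 0.89 and Klf4 at 1.03, and the mean of the list was -0.43 where the median was 0.17. Of the adhesion and chemotaxis receptors there 6 of 20 were higher and 10 were lower (7 and 11 adjusted over the list alone; median log2 -0.16; camera adjusted p = 0.391, adjusted p = 0.789 with an estimated correlation). Itga4 stood at 1.33 and Cd69 at -1.22. Of the cell cycle genes there 1 of 18 were higher and 3 were lower (1 and 3 adjusted over the list alone; median log2 -0.06; camera adjusted p = 0.319, adjusted p = 0.549 with an estimated correlation). Ube2c stood at -1.81. Xist-only cells there had 10 lower of 17 (median -1.10). Of the oxidative phosphorylation genes there 2 of 24 were higher and 11 were lower (2 and 11 adjusted over the list alone; median log2 -0.13; camera adjusted p = 0.0523, adjusted p = 0.325 with an estimated correlation). Uqcrb stood at -0.31 and Cox6c at -0.31. Beside these lists, 37.5% and 24.8% of WT LPS classical monocytes had under 1% mitochondrial UMIs, against 5.90% and 2.28% in KO LPS.

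By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, KO and WT LPS libraries differed in 4352 genes in alveolar macrophages (2013 higher and 2339 lower in KO), 4307 in classical monocytes (2082 and 2225), 4092 in B cells (1896 and 2196) and 3513 in neutrophils (1565 and 1948). The counts were 1865 in endothelial cells, 1005 in interstitial macrophages, 909 in dendritic cells, 733 in T cells, 512 in nonclassical monocytes, 438 in NK cells and 33 in stromal cells. In Xist-only cells they were 1936 in alveolar macrophages, 1193 in classical monocytes, 3261 in B cells, 1424 in neutrophils (443 and 981), 453 in endothelial cells and 308 in T cells (161 and 147). DESeq2 called 570 higher and 1074 lower in alveolar macrophages, 516 and 999 in classical monocytes, 254 and 975 in neutrophils, 81 and 179 in interstitial macrophages, 235 and 498 in endothelial cells and 54 and 171 in T cells. With an estimated correlation 0 of 15 lists passed in any class. Fry called 14 lists in alveolar macrophages, 11 in classical monocytes, 7 in interstitial macrophages and 11 in neutrophils, against 11, 6, 7 and 10 by camera. It called 0 in endothelial cells, NK cells, nonclassical monocytes and stromal cells, against 9, 4, 5 and 4 by camera.

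**Figure D3:**
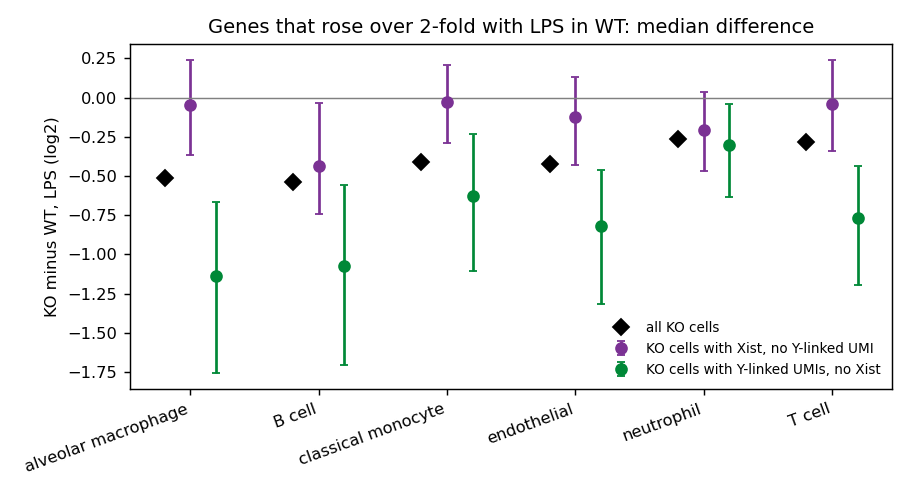
Median difference between KO and WT LPS libraries over the genes that rose more than 2-fold with LPS in WT, for all KO cells, Xist-only KO cells and Y-only KO cells. Bars span the quartiles over genes.

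The LPS response itself was smaller in KO for several inflammatory genes. Il1b rose less in KO by a test of the difference in response, at -1.72 ± 0.14 in alveolar macrophages, -1.44 ± 0.08 in neutrophils, -1.34 ± 0.19 in interstitial macrophages and -1.30 ± 0.13 in classical monocytes (edgeR adjusted p = 1.39e-08, 1.85e-09, 0.000462 and 1.8e-05). Socs3 rose less in neutrophils (-1.82 ± 0.11) and classical monocytes (-1.78 ± 0.13), and Nfkbia in neutrophils (-1.81 ± 0.11) and classical monocytes (-1.31 ± 0.11). In Xist-only cells under LPS the KO minus WT difference of Il1b was 0.14 in alveolar macrophages and 0.19 in classical monocytes, and there 0.12 for Socs3 and 0.21 for Nfkbia, against -0.82, -0.90, -0.81 and -0.86 in all cells. Those all-cell differences are smaller than the differences in response, the rest of which comes from higher KO levels in the single vehicle libraries. The chemokine Cxcl2 had the smallest p in neutrophils (-2.12 ± 0.09) and Ccl5 in classical monocytes (-4.75 ± 0.20), where Lpl went the other way (3.62 ± 0.16). Cxcl2 and Ccl5 stood higher there in the KO than in the WT vehicle library (ratios below), which makes up much of these values. For Cxcl10 in alveolar macrophages the KO vehicle level, 0.131 CPM against 5.18 CPM in WT, was too near 0 for a difference in response to be given. For Socs1 the difference in response was -0.95 ± 0.46 in neutrophils and -0.79 ± 0.41 in classical monocytes, with no call (edgeR adjusted p = 0.375 and 0.301).

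As groups, 14 of 18 genes of the NF-kB pathway and feedback list rose less in KO alveolar macrophages (15 adjusted over the list alone; camera adjusted p = 1.09e-08, adjusted p = 0.362 with an estimated correlation). Of 32 interferon-stimulated genes, 17 rose less and 0 more in KO classical monocytes (23 and 0 adjusted over the list alone; camera adjusted p = 1.71e-08, adjusted p = 0.498 with an estimated correlation). In neutrophils 15 of the 32 rose less and 1 more (18 and 1 adjusted over the list alone; camera adjusted p = 1.29e-07, adjusted p = 0.25 with an estimated correlation). In neutrophils 14 of 19 dissociation and immediate-early genes rose less in KO (15 adjusted over the list alone; camera adjusted p = 8.51e-06, adjusted p = 0.25 with an estimated correlation). In Xist-only classical monocytes under LPS 12 of the interferon-stimulated genes were higher in KO than in WT and 6 lower (median 0.10). Over genes that rose more than 2-fold in WT, the median KO minus WT difference was -0.03 in Xist-only and -0.63 in Y-only classical monocytes, and -0.05 and -1.14 in alveolar macrophages. For the difference in response, fry called 3 of 15 lists in alveolar macrophages against 11 by camera. The counts were 8 against 6 in classical monocytes and 11 against 6 in neutrophils. This comparison rests on 1 vehicle library per genotype. The WT vehicle library carries Y-linked transcripts and the KO vehicle library Xist, so Xist, Ddx3y and Eif2s3y lead most classes.

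Without LPS, KO and WT have 1 library each, so these are values with no test and with intervals of counting error alone. In vehicle neutrophils the granule genes Camp and Ngp stood at KO to WT ratios of 0.0213 (0.00684 to 0.0506) and 0.0807 (0.0507 to 0.123), and the interferon-stimulated gene Oasl2, which lies near Nos1 on the same chromosome, at 0.0671 (0.0397 to 0.107). Neutrophil cluster 4, led by Ltf, Ngp and Camp, held 1 WT and 0 KO vehicle cells. The intervals treat UMIs as separate and do not show whether 1 cell gave most Camp and Ngp UMIs. Thrombospondin, Thbs1 (3.68, 2.51 to 5.55), Oasl1 (3.27, 2.28 to 4.77) and Cxcl2 (3.03, 2.79 to 3.30) were higher. Oasl1 lies close to Oasl2, also near Nos1, but went the other way. In classical monocytes Ccl5 stood at 11.4 (6.89 to 20.2), Retnlg at 4.76 (2.80 to 8.61), Vcan at 0.510 (0.442 to 0.589) and Oasl2 at 0.359 (0.269 to 0.475). In interstitial macrophages Hist1h2ap stood at 9.24 (5.10 to 18.4) and the lysozyme gene Lyz1 at 0.0974 (0.0635 to 0.144). In alveolar macrophages the glutathione transferase Gstp1 stood at 4.59 (3.31 to 6.49). Xist stood there at 755.9 CPM in KO against 0.0806 CPM in WT, and the Y-linked Ddx3y at 0 against 1040 UMIs.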

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

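In this part, the tests by Xist and Y-linked marks, by likeness to the WT vehicle library or its clusters and by gene position on other chromosomes were chosen only after the result was seen.

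A test of the difference between genotypes in the LPS response marked 2363 genes in B cells, 1736 in alveolar macrophages, 1061 in classical monocytes and 814 in neutrophils (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It marked 322 in T cells, 282 in endothelial cells, 259 in nonclassical monocytes, 240 in interstitial macrophages, 77 in dendritic cells, 44 in NK cells and 9 in stromal cells. Each count stands out because WT and KO differ in their change under the same treatment, on 1 vehicle library per genotype. Y-linked transcripts, which the planned comparisons do not use, marked 40.62% and 36.99% of singly marked cells in the KO LPS libraries, far above the 0.0147% of the KO vehicle library.

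LPS-induced genes were lower in KO than in WT LPS libraries. Over genes that rose more than 2-fold in WT, the median difference in alveolar macrophages was -0.51, but -0.05 in Xist-only and -1.14 in Y-only KO cells. In these, classical monocytes, T cells and endothelial cells no Xist-only median lay below -0.12, a pattern consistent with Y-only cells, possibly of another animal, carrying most of the difference, though of genes that fell T cells kept a median of 0.30 out of 0.60. The tables argue against a full account by these cells in neutrophils and B cells (-0.21 and -0.43, but plain CPM scaling moves the median neutrophil gene by 0.33, so in neutrophils this rests on TMM scaling), against Y-only cells being vehicle cells in classical monocytes and endothelial cells (at most 0.671% of them in clusters of vehicle cells), against UMI depth (-0.27 at the nearest to 0 after thinning) and against WT cells of low mitochondrial share (-0.29 without them). Y-only alveolar macrophages lay only 0.45 above the WT vehicle library and 91.7% of them sat with vehicle cells, so carry-over stays open there. It stays open in T cells, where 27.1% of Y-only cells sat with vehicle cells. The T cell median fell from 1.09 to 0.39 in CPM with a bound on free RNA taken off. In B cells carry-over stays open too, as 22.3% of Y-only cells sat with vehicle cells. Y-only neutrophils lay 2.16 above the WT vehicle library in the fit, 0.70 in CPM and 0.28 with the bound taken off. Of 1291 Y-only neutrophils 0 sat with vehicle cells, so the measures disagree there. Whether genotype, sex, dose or time gives the difference stays open as well.

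Across classes, 15 of 9989 genes met a joint rule. Under LPS they were called higher, or called lower, in KO in at least 6 classes, with no opposite call. Between the single vehicle libraries they also leaned the same way in at least 6 classes, with at most 1 class opposite. Among the 15 were the peptide transporter Slc15a2 (median 2.02), Lyst (0.83) and mt-Nd4l (1.33), and Oasl2 (-0.78). DNA of another strain around Nos1 is argued against for the 13 that lie on other chromosomes. It stays open for the others, among them Oasl2 within 20 Mb of Nos1 (6.67% of the 15 against 2.82% of other genes, Fisher's exact p = 0.349). Past the threshold in Xist-only cells of at least 1 class, 93.3% kept their direction. The genes were chosen in the same LPS libraries, and Xist-only B cells alone gave 3261 calls among 10560 genes. That bar is thus too low to decide whether sex of the animals was the cause. The 15 include Gm47283, annotated on the Y chromosome. Against WT LPS cells it was called lower in Xist-only KO cells (median -0.92) and in Y-only KO cells (-2.11), in 6 of 6 classes each. Its difference thus did not follow the sex mark. Only 5 of the 15 kept their direction past the threshold in most classes of Xist-only cells, which argues against sex as the cause of all. Sex stays open for the others, and no biological explanation was tested.

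Interferon-stimulated genes were lower in KO LPS neutrophils, with a median of -0.77. A different mix of neutrophil clusters is argued against, since the median within clusters came no nearer to 0 than -0.25 against -0.44 over all neutrophils on the same per-million scale. UMI depth (-0.75 after thinning) and Y-only cells (-0.67 without them) are argued against as well. A link to the mitochondrial share stays open, as the median mitochondrial share of neutrophils was 0.214% and 0.243% in WT LPS against 0.351% and 0.360% in KO LPS libraries and the alternative of at least 1% was not run in neutrophils. Whether it comes from the genotype, the timing of injection or the handling of 2 libraries a side stays open too.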

How the results depend on the processing

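The alternatives by sex mark, by mitochondrial share and of LPS in WT alone were chosen after seeing the data, the others before. Genes named by rule, and the always named genes where they passed the threshold, kept their direction and their side of it in 4389 comparisons with an alternative, lost the call in 118 and turned in 14. These totals pool LPS and KO against WT over all alternatives. In Xist-only cells, tested for KO against WT, 58 kept both, 21 lost the call and 12 turned. Single lists lost their call in 187 comparisons, all with the correlation estimated. The number of called lists fell there from 105 to 0 for LPS and from 82 to 0 for KO against WT. The 143 that kept their side of the threshold had no call to lose. Counts of genes stayed within 1.5 times the reported count in 141 cases for LPS and 103 for KO against WT, and shares kept their result in 33 and 73. The cause was not tested for any of the changes below, except that thinning and leaving out libraries leave fewer counts to test. The alternative of at least 1% mitochondrial UMIs was not run in neutrophils, of which 85.8% to 95.2% lie below it in each library. The rare classes had fewer counts, with 442129 UMIs in the smallest stromal library against 8126109 in the smallest of alveolar macrophages. A 1.5-fold difference in interstitial macrophages was recovered in 14.9% of simulated genes.

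With DESeq2 in place of edgeR, the KO against WT comparison under LPS gave 1937 in B cells, 123 in NK cells, 225 in T cells, 1644 in alveolar macrophages, 1515 in classical monocytes, 241 in dendritic cells, 733 in endothelial cells, 260 in interstitial macrophages, 1229 in neutrophils and 82 in nonclassical monocytes. The LPS comparison gave 4885 in B cells, 1783 in NK cells, 2111 in T cells, 3866 in alveolar macrophages, 2298 in dendritic cells, 3520 in endothelial cells, 3020 in interstitial macrophages, 2389 in nonclassical monocytes and 817 in stromal cells. Without the low-count filter, the KO against WT comparison under LPS gave 1382 in dendritic cells and 286 in stromal cells. With cells thinned to 1 depth per class, the KO against WT comparison under LPS gave 2667 in B cells, 1120 in endothelial cells, 488 in interstitial macrophages, 2025 in neutrophils and 285 in nonclassical monocytes. The LPS comparison gave 1065 in stromal cells. Without doublet removal, the KO against WT comparison under LPS gave 1064 in NK cells, 1852 in T cells, 3317 in nonclassical monocytes and 290 in stromal cells. The LPS comparison gave 7675 in T cells, 9360 in nonclassical monocytes and 3326 in stromal cells. EdgeR put the KO against WT difference in share at 0.31 in alveolar macrophages (adjusted p = 0.00798), -0.38 in interstitial macrophages (adjusted p = 0.021) and -0.15 in nonclassical monocytes (adjusted p = 0.182). EdgeR put the LPS change in share at 0.38 in dendritic cells (adjusted p = 0.00648) and 0.26 in nonclassical monocytes (adjusted p = 0.0153). The KO against WT difference of Cxcl10 in NK cells turned to -0.73. With at least 500 genes and at most 5% mitochondrial UMIs per cell, edgeR put the KO against WT difference in share at 0.00469 in classical monocytes (adjusted p = 0.961) and -0.14 in dendritic cells (adjusted p = 0.347). EdgeR put the LPS change in share at -0.22 in dendritic cells (adjusted p = 0.136). With cells named one by one, the KO against WT comparison under LPS gave 254 in NK cells, 2957 in endothelial cells, 1188 in nonclassical monocytes and 694 in stromal cells. EdgeR put the KO against WT difference in share at 0.30 in alveolar macrophages (adjusted p = 0.00151), -0.19 in classical monocytes (adjusted p = 0.035), -0.18 in dendritic cells (adjusted p = 0.195), -0.22 in epithelial cells (adjusted p = 0.195), -0.27 in nonclassical monocytes (adjusted p = 0.0161) and -0.11 in plasmacytoid dendritic cells (adjusted p = 0.508). EdgeR put the LPS change in share at 0.28 in dendritic cells (adjusted p = 0.0323), 0.42 in endothelial cells (adjusted p = 0.000212), -0.17 in interstitial macrophages (adjusted p = 0.188), 0.37 in nonclassical monocytes (adjusted p = 0.00077), 0.24 in plasmacytoid dendritic cells (adjusted p = 0.188) and 0.0903 in stromal cells (adjusted p = 0.499). The KO against WT difference of Asprv1 in stromal cells turned to -0.10.

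In Xist-only cells, the KO against WT comparison under LPS gave 308 in T cells, 1936 in alveolar macrophages, 1193 in classical monocytes, 453 in endothelial cells and 1424 in neutrophils. EdgeR put the KO against WT difference in share at -0.10 in NK cells (adjusted p = 0.452), -0.22 in alveolar macrophages (adjusted p = 0.122), -0.57 in classical monocytes (adjusted p = 0.00323), -0.17 in dendritic cells (adjusted p = 0.24), -0.47 in interstitial macrophages (adjusted p = 0.043), 0.48 in nonclassical monocytes (adjusted p = 0.013) and 0.88 in plasmacytoid dendritic cells (adjusted p = 0.0193). The KO against WT difference of Cxcl10 in classical monocytes turned to 0.48, Dhrs3 in alveolar macrophages turned to -0.0856, Il1b in alveolar macrophages turned to 0.14, Il1b in classical monocytes turned to 0.19, Nfkbia in alveolar macrophages turned to 0.26, Nfkbia in classical monocytes turned to 0.21, Nfkbia in endothelial cells turned to 0.0459, Pwwp3a in alveolar macrophages turned to -0.17, Socs1 in classical monocytes turned to 0.10, Socs3 in alveolar macrophages turned to 0.30, Socs3 in classical monocytes turned to 0.12 and Tnf in alveolar macrophages turned to 0.75. In Y-only KO against Xist-only WT cells, the KO against WT comparison under LPS gave 2219 in B cells and 2827 in endothelial cells. With LPS tested in Xist-only KO cells, the LPS comparison gave 2576 in T cells and 2086 in neutrophils. With LPS tested in WT alone, the LPS comparison gave 1428 in stromal cells. In cells with at least 1% mitochondrial UMIs, the KO against WT comparison under LPS gave 484 in T cells, 526 in dendritic cells, 466 in interstitial macrophages, 165 in nonclassical monocytes and 5 in stromal cells.

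Leaving out 1 LPS library at a time, with the lone library assumed to vary like the other groups, gave ranges of 179 to 434 in NK cells, 303 to 611 in T cells, 540 to 1042 in dendritic cells, 111 to 438 in nonclassical monocytes and 0 to 266 in stromal cells for KO against WT under LPS, and of 436 to 2625 in stromal cells for LPS. Without either KO LPS library, edgeR called 0 genes in stromal cells, with 500 and 464 genes at an unadjusted p under 0.05, while DESeq2 called 40 with all libraries. The KO against WT difference in share ranged over 0.77 to 0.82 in B cells, -0.63 to -0.46 in NK cells, 0.67 to 0.87 in T cells, -0.36 to -0.20 in dendritic cells, 0.53 to 0.71 in endothelial cells, 0.82 to 1.25 in epithelial cells, -0.40 to -0.36 in neutrophils, 0.82 to 1.44 in platelets and 0.73 to 1.26 in stromal cells.

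With replicate numbers as a block, the KO against WT comparison under LPS gave 685 in NK cells and 67 in stromal cells. Correlations between libraries of equal number ran from -0.06 to 0.12, so the numbers were not used as pairs; the block changed no other count by over 1.5 times.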

Other observations

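In this part, the comparisons of Y-only KO LPS cells with the WT vehicle library and its clusters were chosen only after the result was seen.

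Classical monocytes held a cluster that came almost only from KO LPS lungs. Cluster 18 held 554 and 395 cells of the KO LPS libraries against 10 and 17 of the WT LPS libraries. Endothelial cluster 44 held 157 and 109 KO LPS cells. The sex marks of cells in clusters 18 and 44 are not reported here. Among alveolar macrophages of the KO LPS libraries, 549 and 371 cells sat in cluster 2 with the vehicle cells and 501 and 434 in cluster 6 with the WT LPS cells. This split followed the sex mark, as 91.7% of Y-only but 3.41% of Xist-only KO LPS alveolar macrophages sat in cluster 2.

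Y-only cells of the KO LPS libraries were compared with the WT vehicle library over genes that rose more than 2-fold with LPS in Xist-only KO cells. In CPM they lay above it by a median of 0.91 in classical monocytes, 0.98 in endothelial cells, 1.09 in T cells and 0.47 in alveolar macrophages. With an upper bound on free RNA taken off, the lowest UMIs per cell among other large classes, the medians were 0.76, 0.85, 0.39 and 0.19. Of Y-only KO LPS alveolar macrophages 671 of 732 sat in the cluster of vehicle cells, of T cells 39 of 144, of B cells 29 of 130 and of classical monocytes 0 of 588. Of Xist-only KO LPS cells, 3.41%, 0.315%, 0.429% and 0% of these classes sat there. Cells with both marks made up 11.04% and 9.78% of marked cells in the KO LPS libraries.

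The mitochondrial transcript mt-Nd4l was higher in KO in 11 of 11 classes. Over the whole library, Socs1 stood at 13.1 CPM in the WT vehicle and 18.5 CPM in the KO vehicle library. Mitochondrial shares differed between the LPS groups: 29.4% and 11.5% of WT LPS alveolar macrophages had under 1% mitochondrial UMIs, against at most 0.485% in the other libraries. The median of Malat1, a nuclear RNA, was 20.9 and 33.7 per 10000 UMIs in WT LPS classical monocytes and 45.6 and 54.8 in KO LPS ones.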
